A study of Rattus norvegicus with 4 samples.

How the data were processed

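Total RNA of NR8383 cells was measured on 4 arrays, 1 per biological replicate of a single group. Per the labels' protocols, cells after 20 passages had been grown with 15% serum, seeded for 48 h in flasks of 25 cm2, and 100 ng of RNA with an integrity number above 7.5 was labelled with the dye Cy3. The labels add the letters ALI to the condition without spelling them out, and they are not interpreted here. Per the file headers, these were one-colour Agilent scans on a single slide with a single scan, so slide and scan could not be tested as batches, and the array's position is the replicate. Per the submitters' processing notes, the scans were quantified with Agilent Feature Extraction 11.0.1.1. The deposited values are spot intensity values on a linear scale, per the file headers: a processed signal after the software's background handling, and the median foreground and background signals, none of them scaled between arrays. Spots that the software did not call significant carried a processed signal close to their own error estimate (median ratio 0.997 on replicate 1), so such values were treated as below background.

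Of 62976 spots per array, 4259 control spots were left out, as were spots marked as outliers (between 440 and 1206 per array). No spot was saturated. Spots of 1 probe were averaged, which gave 45598 probes, with 318 left out because every spot was an outlier on some array. The main setting was the log2 processed signal minus each array's 75th percentile over non-control probes. The share of probes above background differed between arrays, so the percentile over probes detected on all 4 arrays was added as an alternative after seeing the data. Genes were named by matching unversioned accessions to RefSeq symbols of the GRCr8 assembly, used for names only. It named 17614 of 40539 accessions and 21109 probes, and 24489 probes stayed unnamed and entered no gene count. No coordinates are given, since the array's annotation is on another build.

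A probe was detected if the majority of its spots were flagged well above background on each of the 4 arrays, and a gene if any of its probes was. A gene's level was the mean of its detected probes. Of 3631 genes with several probes, 925 had probes on both sides of the call. A total of 31 gene lists with 575 members (535 measured) were fixed before the data were examined. They covered macrophage identity, function and stress responses, reference genes, and markers of other cell types. Detected shares were tested with two-sided Fisher's exact tests against all other named genes, Benjamini-Hochberg adjusted over the 31 lists. Genes of a list are not independent, so these p-values describe the lists on these arrays. Shifts and spreads of lists with at least 5 detected members used 10000 random lists drawn within 20 bins of mean level, with the central 99% as the range. Hypervariable genes were sought with limma's robust fit of the per-gene variances, with the mean level as covariate and an adjusted p under 0.05. Computation used R 4.3.3, limma 3.58.1, matrixStats 1.5.0 and the data.table package (version 1.17.8), and figures matplotlib 3.10.9.

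Named genes followed a rule set before the data were examined: of each list the first 3 members detected on all arrays and the first 2 detected on none, all exceptions in lists with 3 or fewer, and the 5 largest deviations of 1 array in each direction. Genes named outside it are said to have been chosen after their values were seen. Alternatives were each replicate left out, 2 looser detection calls (the positive-and-significant flag, and a limma test against the 95th percentile of negative controls), detection on at least 3 arrays, normexp with an offset of 50 on the median signals, quantile normalization, the median of detected probes, no filter on dim probes, the first probe of a gene and a background of curated symbols. Normexp was planned on mean signals, and the median signals stood in for them.

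Simulated data with known answers tested the hypervariable fit, list shares and shifts, limma detection, and the SD between and within arrays. The main detection call, the normalization and the list spreads were not simulated. In 8772 simulated genes with the observed spread of variances over 4 arrays, the hypervariable test recovered 0% of 50 genes moved on 1 array by 1, 2, 4 or 6 log2 units. With the spread of replicates 2 to 4 it recovered 4% at 1, 92% at 2 and 100% at 4 and 6. The list test found 40% of simulated lists of 15 genes moved by 0.2 and 95% of those moved by 0.4. Its range was left by 3 of 160 unmoved pairs. All 10 lists made with 18 of 20 genes detected and all 10 made with 4 of 20 were called, and 1 of 20 unchanged lists was. Milder shares and smaller lists were not simulated, so the power for them is not known. The 75th percentile signal was between 25.6 and 45.5 times the 95th percentile of negative controls, and it was lowest on replicate 1.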

Results

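NR8383 is an established rat alveolar macrophage line, derived from cells washed out of a normal rat lung, that grows as a mix of adherent and floating cells. The series measured its transcripts in 1 condition, cells held for 4 h in culture medium with 10% fetal bovine serum, on 4 one-colour arrays from 4 biological replicates. With 1 group there was no comparison between treatments. The design allows 3 questions: which genes the line expressed in this condition, how closely the replicates agreed, and which genes or gene groups stood apart on 1 replicate. Between 50.9% and 58.9% of the 58717 spots for rat transcripts were well above background on an array, and the 75th percentile of signal was 83.4 on replicate 1, 112 on replicate 2, 126 on replicate 3 and 167 on replicate 4. The number of arrays limits the precision. Of 16506 named genes measured, 8772 (53.1%) were detected, meaning well above background on all 4 arrays, and 5684 (34.4%) were detected on none. The 2 looser detection calls gave 11043 genes (positive-and-significant flag) and 11418 genes (limma against negative controls). Levels are given as log2 signal over the array's own 75th percentile, mean ± SD, n = 4, and levels of different genes cannot be set against each other.

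The line expressed most of the macrophage genes that were looked for. Of 30 genes of macrophage and myeloid identity, 23 were detected (76.7%, adjusted p = 0.0221, Fisher's exact test against all other genes), and of 20 alveolar macrophage markers 17 were (85.0%, adjusted p = 0.0158). They included the lysosomal glycoprotein Cd68 at 7.44 ± 0.17, the receptor for the growth factor that sustains macrophages, Csf1r, at 1.84 ± 0.39, and the myeloid transcription factor Spi1 at 3.78 ± 0.11. The nuclear receptor Pparg, required for alveolar macrophage development, lay at 6.16 ± 0.48, the mannose receptor Mrc1 at 2.69 ± 0.69 and the lectin Siglec5 at -0.43 ± 0.96. Exceptions among the alveolar markers were the scavenger receptor Marco, well above background on 1 array, Csf2rb, a receptor chain for granulocyte-macrophage colony-stimulating factor, on 3 arrays, and Car4 on none. The transcription factor Cebpa was well above background on no array. Chosen after their values were seen, the scavenger receptor Cd163 and the complement gene C1qc were well above background on no array, and C1qa and C1qb on 2. Without replicate 1 the macrophage identity list no longer passed (adjusted p = 0.0547), with the same share.

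Gene groups of general upkeep and of growth were nearly complete. All 23 cell cycle genes were detected (adjusted p = 1.56e-05), with the proliferation marker Mki67 at 2.57 ± 0.19, the kinase Cdk1 at 4.73 ± 0.68 and its partner cyclin Ccnb1 at 1.99 ± 0.33. All 17 reference genes were detected (adjusted p = 0.00037), among them Actb at 9.05 ± 0.26, Gapdh at 7.99 ± 0.06 and Hprt1 at 3.95 ± 0.09. Of the lysosome list 20 of 21 genes were detected (adjusted p = 0.000374), with the proteases Ctsd at 10.05 ± 0.06 and Ctsb at 9.24 ± 0.17 and the membrane protein Lamp1 at 5.69 ± 0.15, and Ctsk was the exception. The sterol and lipid list had 19 of 21 (adjusted p = 0.00258), with the cholesterol exporter Abca1 at 0.11 ± 0.29, and without the fatty acid enzymes Fasn and Scd.

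Stress and defence genes were detected in this serum control as well. Detected genes made up 19 of 20 in heat shock and unfolded protein response (adjusted p = 0.00051), where the chaperones Hspa5 and Hspa1a lay at 6.27 ± 0.17 and -0.70 ± 0.25 and Ern1 was the exception. Hspa1a was detected by 1 of its 2 probes. Of the NRF2 and antioxidant defence list 21 of 24 genes were detected (adjusted p = 0.00262, Fisher's exact test). The heme-degrading enzyme Hmox1 lay at 6.89 ± 0.71, Nqo1 at 0.16 ± 0.06 and Gclc at 3.88 ± 0.08. Gclm and Gpx3 were well above background on no array and Osgin1 on 3. Metal handling had 15 of 17 (adjusted p = 0.00961), with the metallothioneins Mt1 at 5.52 ± 0.31 and Mt2A at 2.01 ± 0.39 and the phagosomal metal transporter Slc11a1 at 3.24 ± 0.32, but neither the iron exporter Slc40a1 nor Mt3, and the list lost its call under limma detection (adjusted p = 0.0656). Interferon-stimulated genes had 18 of 19 (adjusted p = 0.000741), with Isg15 at 2.35 ± 0.12, Mx1 at 1.42 ± 0.68 and Irf7 at 2.90 ± 0.78, and without Ifit1. Hypoxia and glycolysis had 15 of 18 (adjusted p = 0.0322), with Slc2a1 at 5.27 ± 0.39 and Ldha at 8.10 ± 0.15 and with Vegfa below background on all arrays. That call was lost when the first probe stood for a gene (adjusted p = 0.0566). The DNA damage response list had 14 of 17 (adjusted p = 0.0495), with Cdkn1a at 2.78 ± 0.08 and Mdm2 at 1.62 ± 0.29. Its call was lost without replicate 1 (adjusted p = 0.0877) and without replicate 2 (adjusted p = 0.0531). Detection on at least 3 arrays (adjusted p = 0.0820) and a background of curated symbols (adjusted p = 0.0503) also removed it.

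The inflammatory programme was detected in part. Of 25 cytokines and mediators 14 were detected, a share of 56.0% that was not called different from that of other genes (adjusted p = 0.901, Fisher's exact test). The cytokines Tnf, Il1b and Il1a were present at 2.00 ± 0.77, 6.75 ± 0.57 and 5.66 ± 0.25, while Il6 and the prostaglandin synthase Ptgs2 were below background on every array and under both looser detection calls. Of the alternative activation list 9 of 17 were detected (adjusted p = 1), including Arg1 at 3.80 ± 1.06 and the interleukin antagonist Il1rn at 6.73 ± 0.40, but not Il10 or Retnla. Pattern recognition and inflammasome genes reached 17 of 22 (adjusted p = 0.0558), with the receptors Tlr4 at 1.17 ± 0.27 and Tlr2 at 4.80 ± 0.33 and the adaptor Myd88 at 5.19 ± 0.16. Antigen presentation reached 13 of 19 (adjusted p = 0.388), with the class I gene RT1-A1 at 9.03 ± 0.39 and the class II genes RT1-Db1 and RT1-Bb at -0.78 ± 0.31 and -2.17 ± 0.11, while the class II invariant chain Cd74 and RT1-Da were not well above background on any array.

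Other functional lists were not called different from all other genes in Fisher's exact tests. Immediate early genes had 13 of 19 detected (adjusted p = 0.388), with Jun at 3.14 ± 0.43 and Junb at -0.39 ± 0.40. The NADPH oxidase list had 6 of 9 (exact test, adjusted p = 0.639), and these included the phagocyte subunits Cybb at 2.52 ± 0.27, Cyba at 9.07 ± 0.22 and Ncf1 at 3.37 ± 0.16 but not the non-phagocyte oxidases Nox1, Nox4 and Duox2. Scavenger and phagocytic receptors had 8 of 16 (adjusted p = 0.895), with Msr1 at 2.27 ± 0.19 and Cd36 at 4.56 ± 0.18. Matrix metalloproteinases and inhibitors had 7 of 17 (adjusted p = 0.461), with the macrophage elastase Mmp12 at 2.10 ± 0.68. The aryl hydrocarbon list also had 7 of 17 (adjusted p = 0.461), and both the receptor Ahr and its target Cyp1a1 were below background. Of the function and stress genes named as not detected, Marco, Csf2rb, Cebpa, Scd, Ern1, Osgin1, Mt3, Il10 and Nox1 passed both looser calls, the positive-and-significant flag and limma against negative controls, and RT1-Da passed the limma call.

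Markers of several other cell types were mostly not well above background on all 4 arrays. The detected share was lower than in other genes for airway and alveolar epithelium other than type 2 cells (2 of 15, adjusted p = 0.00961, Fisher's exact test), neutrophils and mast cells (1 of 15, adjusted p = 0.00146), fibroblasts and smooth muscle (3 of 16, adjusted p = 0.0221) and neurons, liver and muscle (4 of 18, adjusted p = 0.0221). Genes well above background on no array included Epcam and Scgb1a1 of epithelium, Elane and S100a8 of neutrophils, and Col3a1 and Lum of fibroblasts. The detected ones were Ager and Foxj1, the antimicrobial peptide gene Camp at 2.28 ± 0.37, then Col1a2, Dcn and Fap, and Gfap, Tnnt2 and Ckm among others. Foxj1 was detected by 1 of its 2 probes. Under the looser positive-and-significant call 1 of these 4 lists stayed lower, and under the limma call against negative controls 2 did. That limma call detected 56.25% of the fibroblast and smooth muscle list and 55.6% of the neuronal, liver and muscle list. With spots still required to be well above background, the lower share of fibroblast genes lost its call without replicate 1 (adjusted p = 0.128) and that of neuronal, liver and muscle genes without replicate 2 (adjusted p = 0.0591). No difference in share was called for alveolar type 2 cells (3 of 9, exact test, adjusted p = 0.461), T and NK cells (7 of 16, adjusted p = 0.601), B cells (3 of 7, exact test, adjusted p = 0.850), dendritic cells (4 of 9, exact test, adjusted p = 0.852), endothelium (7 of 13, adjusted p = 1) and erythroid cells (2 of 9, exact test, adjusted p = 0.160). Lists this small cannot show that a share was equal. The erythroid share, 22.2%, was that of the larger neuronal, liver and muscle list, which was called lower. Surfactant genes Sftpa1 and Sftpb were below background, whereas the surfactant gene Sftpd was detected at -1.71 ± 0.73, and Napsa lay at 5.90 ± 0.41 and Etv5 at 3.50 ± 0.17. Endothelial Vwf lay at 4.16 ± 0.17 on 1 of its 2 probes, and B cell Pax5 at 0.35 ± 0.11. The other Vwf probe was not well above background on all 4 arrays, so its probes disagreed.

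**Figure D1:**
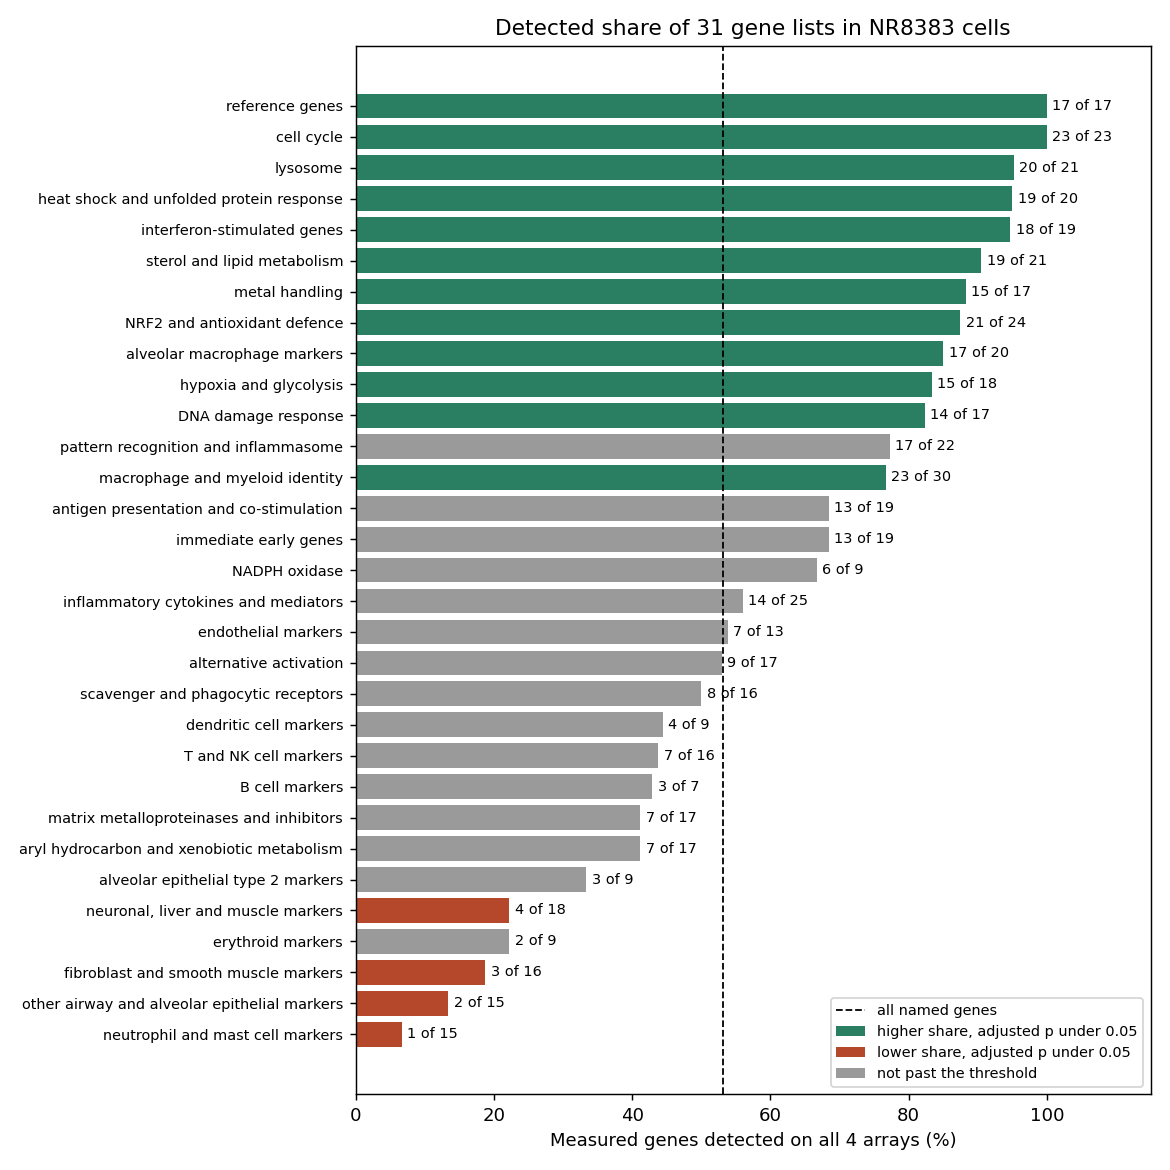
Percentage of each list's measured genes that were well above background on all 4 arrays, with the counts beside the bars and colours for Fisher's exact test with Benjamini-Hochberg adjustment. The dashed line marks the 53.1% of all named genes; 12 lists had a higher share and 4 a lower one.

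Levels correlated strongly between replicates, with replicate 1 farther from the rest. The median SD of a detected gene between the 4 arrays was 0.24 on the log2 scale (interquartile range 0.15 to 0.36), and without replicate 1 it was 0.15. Across the 8772 detected genes, which are not independent replicates, Pearson's r was between 0.986 and 0.993 for pairs among replicates 2 to 4 and between 0.969 and 0.978 for pairs with replicate 1. Replicate 1 was the array farthest from the gene's mean for 54.7% of detected genes, against 25% by chance. For 1044 detected probes printed many times per array, the SD between arrays (0.16) was 1.40 times the SD between spots of 1 array (0.12). It was 4.39 times the standard error of the mean over those spots (0.037), which covers only the noise between spots of 1 array. Under normexp on median signals the first ratio was 0.918.

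On replicate 1 the cytokine genes lay lower, and cell cycle and interferon-stimulated genes higher, than on the other arrays. Each list's median deviation from the 4-array mean was set against 10000 random lists matched on level. The cytokine list lay at -0.68 on replicate 1, below all random lists, with 9 of 14 genes lower and 5 higher, and at 0.38 on replicate 2 and 0.17 on replicate 4. Tnf read 0.88 on replicate 1 and between 2.22 and 2.62 on the others, and Il1b read 5.93 against 6.92 to 7.24. Il1a did not stand apart, at 5.72 against 5.29 to 5.83. The cell cycle list lay at 0.36 on replicate 1 (percentile 99.97, 22 of 23 genes above their mean), with Cdk1 at 5.74 there and between 4.29 and 4.46 elsewhere. The interferon list lay at 0.41 (percentile 99.99, 14 of 18 genes), with Mx1 at 2.43 against 0.98 to 1.20 and Irf7 at 4.00 against 2.33 to 2.94. Isg15 did not stand apart, at 2.43 against 2.24 to 2.46. Without replicate 2 the interferon list was inside the random range (0.28). Chosen after their values were seen, the chemokine Cxcl10 lay higher on replicate 1 than the mean of the others (1.29) and the interferon-stimulated Usp18 lower (-2.31), each against its list. Heat shock and unfolded protein response genes lay at -0.17 on replicate 1 (percentile 0.3), a shift lost under several alternatives, among them without replicate 2 (-0.087) and without the spots of a dim patch on replicate 4 (-0.12).

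Further shifts fell on other arrays. On replicate 2 the cell cycle, interferon, sterol and alveolar macrophage lists lay at -0.22, -0.26, -0.25 and -0.14 and the matrix metalloproteinase list at 0.28, and on replicate 3 the cell cycle list lay at -0.12. In all, 12 of 92 pairs of a list and an array lay outside the central 99% of random lists, where lists of unrelated genes would give 0.92. Genes of these lists are not independent, so chance can give more than that. Deviations are taken from a mean that includes every array, so a low replicate 1 raises the others. Without replicate 1 the number was 5, with the cytokine (0.18) and sterol (-0.13) shifts on replicate 2 among them. The cell cycle (-0.048), interferon (-0.046), alveolar macrophage (-0.038) and metalloproteinase (0.14) lists on replicate 2 and the cytokine list on replicate 4 (0.033) then lay inside the random range, and the cell cycle list on replicate 3 turned to 0.055. Under normexp correction the cell cycle list on replicate 1 lay at 0.12, inside the random range, and with undetected genes included the cytokine list lay at 0.056.

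**Figure D2:**
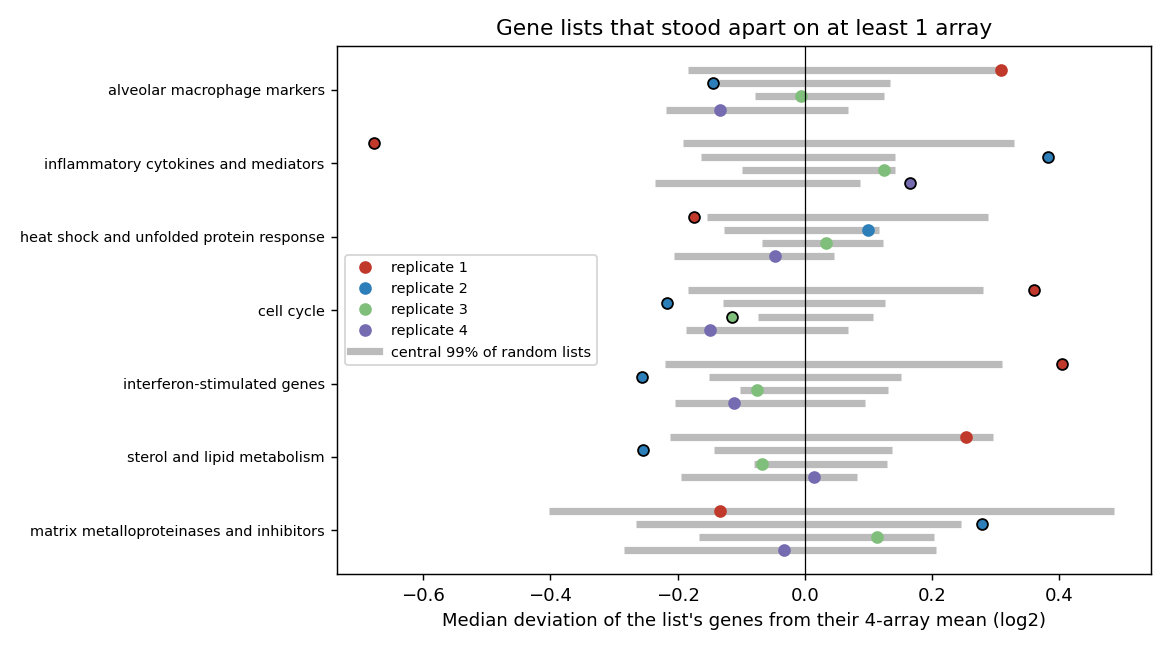
Median deviation (log2) of each list's detected genes from their 4-array mean on replicates 1 to 4, for the lists that lay outside the central 99% of 10000 matched random lists (grey bars) on at least 1 array; black outlines mark those points. The cytokine list lay at -0.68 on replicate 1, and the cell cycle and interferon lists at 0.36 and 0.41.

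**Figure D3:**
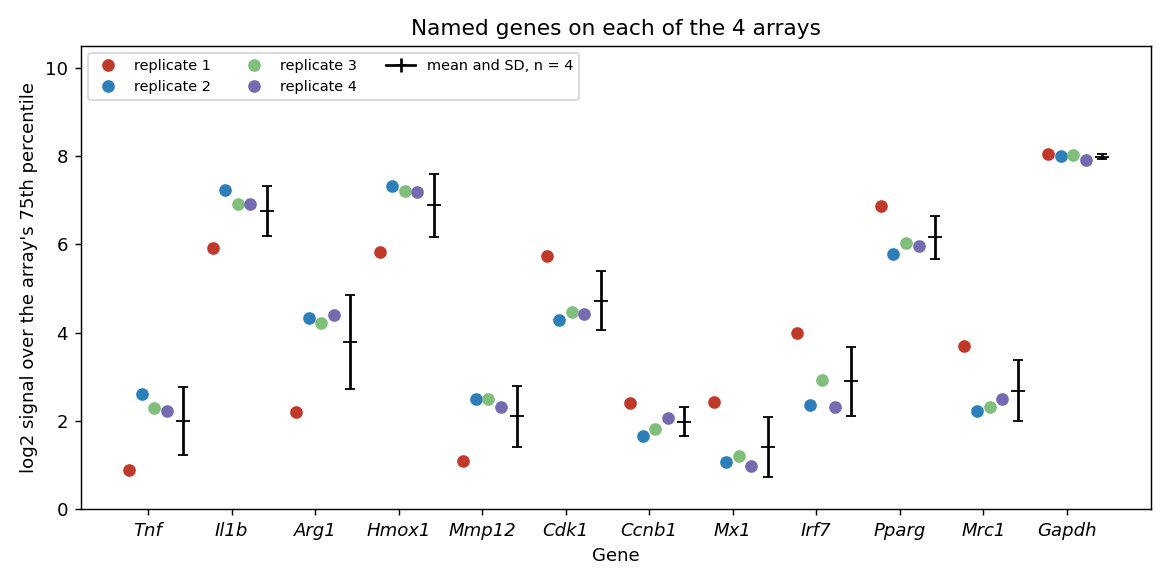
Level of 12 named genes (log2 signal over the array's 75th percentile) on each array, with the mean and SD of the 4 replicates in black; levels compare arrays within a gene, not genes with each other. Tnf, Il1b, Arg1, Hmox1 and Mmp12 were lowest on replicate 1 and Cdk1, Ccnb1, Mx1, Irf7, Pparg and Mrc1 highest, while Gapdh varied by an SD of 0.06. The genes are a selection, and Il1a and Isg15 of the same lists, which did not stand apart on replicate 1, are not shown.

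The spread between replicates was high for 3 lists. The median SD of the cytokine genes was 0.55, above the 99th percentile of random lists (0.35), that of the interferon-stimulated genes was 0.41 (random 0.35) and that of the DNA damage response list 0.40 (random 0.37). Without replicate 1 the interferon and DNA damage values were both 0.14 and no longer high. The DNA damage value was also no longer high without replicate 2 (0.349) or without replicate 4 (0.354). Under normexp on median signals neither was high, at 0.291 for interferon and 0.246 for DNA damage. No single gene was called hypervariable by limma's robust variance fit (0 of 8772 at an adjusted p under 0.05, with 419 genes at an unadjusted p under 0.05). The test made no calls on simulated genes moved by as much as 6 log2 units on 1 of the 4 arrays, so this count cannot show that genes agreed. Without replicate 1 it called 112 genes.

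The largest deviations of single genes on 1 array came from 1 place on the array surface. Lower on replicate 4 than the mean of the other arrays were Uckl1 by -5.09, Hsd17b11 by -5.05, Copb1 by -3.94, Rfxank by -3.83 and Cebpg by -3.78, and their spots lay within rows 166 to 216 and columns 73 to 88. All 77 detected probes more than 2 log2 units lower on replicate 4 lay in that patch, which was drawn around them. Inside it replicate 4 lay at a median of -2.11 and replicate 3 at -0.84 from replicates 1 and 2, and outside the patch and its margin at -0.036 and 0.020. Deviations of Cebpg on replicate 2 (2.81) and of Slc25a17 (2.77) and Uckl1 (2.76) on replicate 1 include the low values of replicate 4. Those of Adam7 (2.70) and Apobec1 (2.67), which encodes a cytidine deaminase, on replicate 1 do not. With its margin the patch held probes of 895 named genes, among them Siglec5, Ddit3, Scarb1 and Hif1a of the lists. Of the 112 genes called hypervariable without replicate 1, 95 had a probe there. Without the patch and its margin 8464 genes were detected, Hif1a no longer among them, and 10 lists instead of 12 had a higher share, as hypoxia and glycolysis (adjusted p = 0.102) and the DNA damage response (adjusted p = 0.0528, Fisher's exact tests) lost their calls.

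**Figure D4:**
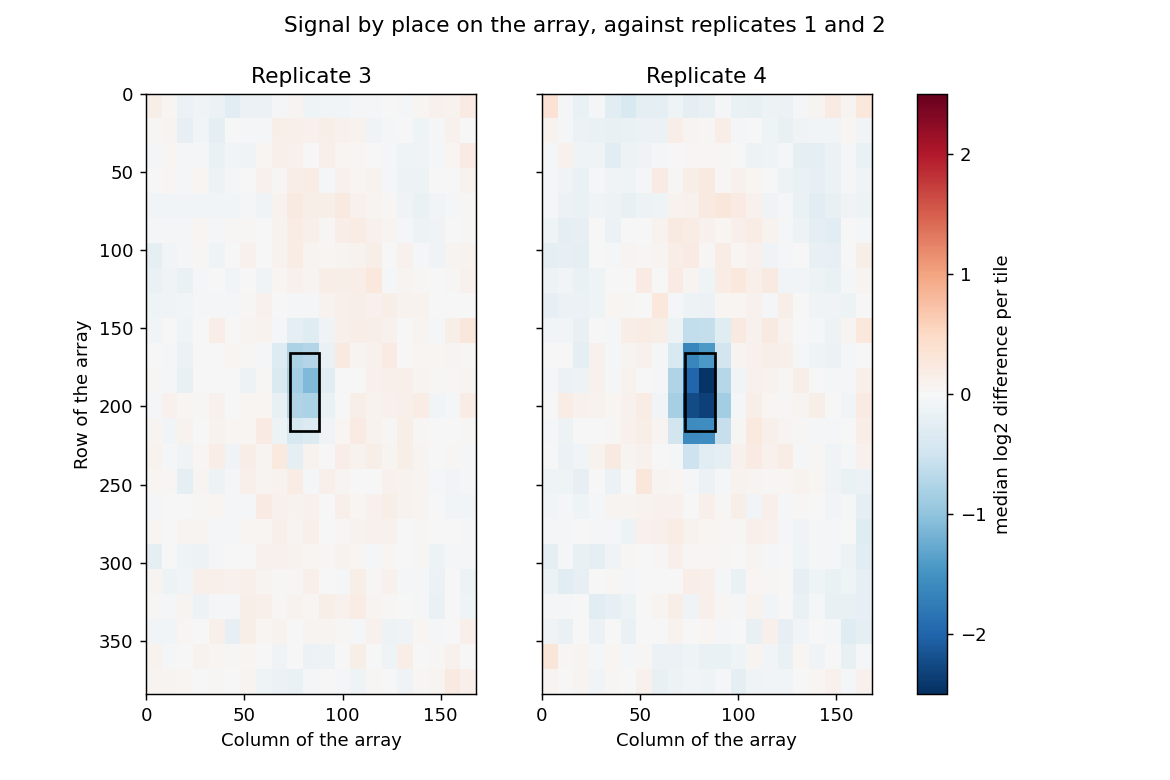
Median log2 difference from replicates 1 and 2 in tiles of 16 rows by 8 columns across the array, for replicate 3 (left) and replicate 4 (right), over probes detected on all 4 arrays. The black box marks rows 166 to 216 and columns 73 to 88, where the medians were -0.84 on replicate 3 and -2.11 on replicate 4.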

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

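The tests of the patch on the array's surface by odd and even spots were chosen only after the drops on replicate 4 had been seen.

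A gap rule for 4 samples picked out values in which 1 array lay far from the other 3. It was applied to 123 measures and picked 9, where chance picks about 5% of groups. That rate does not hold for the genes named for a large deviation on 1 array, of which Apobec1 alone was picked. On replicate 1, relative to the mean of the others, Arg1 lay at -2.12, Hmox1 at -1.42 and the elastase Mmp12 at -1.35, while Cdk1 lay at 1.35, Mx1 at 1.35, the transcription factor Batf3 at 0.88 and Apobec1 at 2.67. On replicate 2 the cholesterol exporter Abca1 lay at 0.58. On replicate 4 the median of the DNA damage response list lay at 0.18. In data outside the main measurement, 2 of 96 probes for the ERCC spike-in set, which the labels do not mention, were above background on all 4 arrays.

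The lower cytokine and higher cell cycle and interferon lists on replicate 1, the dimmest array, were weighed first. A trend of signal with brightness was removed by cyclic loess, and all 3 lists still lay outside the random range. They had been picked for lying outside random lists already matched on level. This outcome was therefore nearly fixed beforehand and cannot decide on such a trend. Among list members with at least 2 detected probes, 11 of 14 had the first 2 on the same side. Of all 1654 such genes 68.7% did so on replicate 1, where noise of single probes alone gives an even split. This argues against such noise as the whole cause of that array's deviations across genes. For the 3 lists it stays open, as they had been picked for the shift that these probes make up, and 1 of the 14, Tnf, was a cytokine. Under normexp on median signals, which changes the signal and its correction together, the cell cycle list lay inside the random range (0.12). Handling of that culture, RNA preparation and array position stay open, and as the labels give no difference between replicates, no biological explanation of these 3 lists was tested, only target lists on other genes.

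The probes far lower on replicate 4 alone were weighed next. A box drawn around those with odd spot numbers held 81.0% of the 42 with even spot numbers, though 1.30% of spots lie in the whole patch, as a local defect of the array needs. Less transcript in replicate 4 is argued against: 28 other detected probes of the same genes outside the patch had a median deviation of -0.065 (interquartile range -0.19 to 0.089). In the patch 14.3% of replicate 4's spots were marked as outliers by the software, against 1.89% elsewhere, so most of the dim spots carry no mark. What dimmed the same place on replicates 3 and 4 stays open.

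The genes detected on only some arrays were set beside array brightness. Of the 688 genes detected on exactly 3 arrays, 73.1% were missed on replicate 1, the dimmest (95% exact binomial interval 69.6% to 76.4%), where equal arrays give 25%. Of the 843 detected on exactly 1 array, 56.6% were detected on replicate 4, the brightest. Brightness and detection come from the same spot signals, and replicate 1 had the fewest detected genes (9131, against 9558 to 10349 elsewhere). This outcome was therefore nearly fixed beforehand. It cannot tell array brightness from fewer genes expressed in replicate 1. Replicate 1 also differs in its gene lists, so part of its share may come from those genes. No biological explanation was tested.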

How the results depend on the processing

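Alternatives that use the dim patch, cyclic loess or a percentile over detected probes were chosen after seeing the data. No paired analysis was possible because the series has 1 group. Leaving out saturated spots removed none and gives no value. Of 112 recomputed counts and spreads 99 stayed within their range. For counts that range was wide, as it held the 11043 and 11418 genes of the 2 looser detection calls against 8772. Leaving out 1 replicate gave between 0.15 (without replicate 1) and 0.26 for the median SD, 1.19 (without replicate 4) and 1.48 for the ratio of between- to within-array SD, 0 and 112 (without replicate 1) hypervariable genes, and 5 (without replicate 1) and 14 list shifts. Without replicate 1, the patch and its margin these were a median SD of 0.15, 19 hypervariable genes and 6 shifts. Lists with a lower share numbered 1 under the positive-and-significant flag and 2 under limma against negative controls. Normexp on median signals gave a ratio of 0.918 and 1 list with a high spread. With no filter on dim probes the median SD was 0.34 and 2 genes were hypervariable. The cause was not tested in these cases. Of 176 recomputed list shares none turned and 17 lost their call; of 188 list shifts 28 were lost and 3 turned. The cell cycle list on replicate 3 was -0.18 without replicate 2 and turned to 0.055 without replicate 1, with or without the patch, and the cytokine list on replicate 1 to 0.056 with no filter on dim probes, where genes below background enter. Of 59 named genes not detected on all 4 arrays, 20 passed the positive-and-significant flag and 23 limma against negative controls. Signal over background was lowest on replicate 1, as was the number of detected genes.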

Other observations

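All genes and tests of this part were chosen after the shifts on replicate 1 had been seen. Outside the patch and its margin, 220 genes lay more than 1 log2 unit higher and 170 more than 1 lower on replicate 1 than the mean of replicates 2 to 4, among the 6963 detected genes whose other 3 values lay within 0.5 of each other. The same rule gave 2 higher and 6 lower of 4736 genes on replicate 2, 1 higher of 4354 on replicate 3, and 6 higher and 4 lower of 4677 on replicate 4, where fewer genes qualify because replicate 1 must lie close to the others. Lower on replicate 1 were Trib3, a pseudokinase gene induced by the integrated stress response (-2.55), Nupr1 (-2.13) and the amino acid transporter Slc38a2 (-1.72). The chemokine Ccl2 (-1.92), the zinc exporter Slc30a1 (-1.71), the lipid droplet protein Plin2 (-1.49) and the receptor Il7r (-2.07) were lower too, as was Usp18 (-2.31), against the rise of the interferon list. Higher were the inflammasome adaptor Pycard (1.64), the polymerase subunit Pold1 (1.51), the interferon-inducible Ifi47 (1.57), the kinase subunit Pik3cd (2.10) and the sterol regulator Srebf2 (1.13).

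Because Trib3, Nupr1 and Slc38a2 are targets of the transcription factor ATF4, a hypothesis was that genes of the amino acid response were less expressed in replicate 1. A list of 26 other ATF4 targets, from which genes already seen had been left out, had 21 detected members. Their median deviation on replicate 1 was -0.37, below all random lists, and 17 of 21 lay lower than the mean of the other arrays. Examples are Atf5 (-0.78), the transfer RNA synthetase genes Sars1 (-0.73) and Aars1 (-0.73), the serine synthesis genes Phgdh (-0.64) and Psat1 (-0.60), and the transporter subunit Slc3a2 (-0.70). The exceptions were Ddit4, Slc1a5, Mars1 and Cars1, the last of which has its probe in the patch. This may reflect a lower amino acid response in that culture, but a difference in medium, cell density or handling was not measured.

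A parallel hypothesis was that NF-kB target genes outside the 31 lists went with the cytokines. As first written, the list held Sdc4 (-2.01), Clic4 (-1.44) and Ebi3 (1.88), whose values had already been seen, and its 20 detected members had a median deviation of -0.27 on replicate 1 (percentile 0.26), outside the random range. These 3 genes were taken out after that result, as seen genes had been for ATF4. The 17 detected genes left had a median of -0.25 (percentile 0.68), inside the range of -0.26 to 0.31, so the test leaves the hypothesis undecided. Of the 17 genes 12 lay lower than the mean of the other arrays, among them Bcl2a1 (-1.30), Cflar (-1.23) and Icam1 (-0.87), while Map3k8 (0.71) and Tnfaip2 (0.43) lay higher. Bcl2a1 was itself among the genes that the rule above had found lower on replicate 1. The remaining list is therefore not free of genes from that search. On replicate 2 the ATF4 list and the remaining NF-kB list lay above the random range, at 0.16 and 0.19, as did the ATF4 list on replicate 4 (0.062).

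Deviations were shared by different probes of a gene most on replicate 1. Over 1654 genes with at least 2 detected probes, Pearson's r across genes between the deviations of the first 2 probes was 0.501 on replicate 1, 0.308 on replicate 2, 0.250 on replicate 3 and 0.189 on replicate 4. Genes are not independent replicates, and no test was made of the difference between arrays. Of the probes without a gene name here, those for Ensembl transcripts were detected in 42.6% of cases and those for other GenBank records in 25.7%. Among probes for predicted non-coding RNAs, most of them unnamed, 14.3% were detected, against 52.7% of probes for RefSeq mRNAs.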
